A study of Chiloscyllium plagiosum with 5 samples.

How the data were processed

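Small RNA of shark liver was sequenced in 5 libraries: normal liver, and liver taken 3, 6, 12 and 24 h after partial hepatectomy, with 1 library per group as the labels assign them. Per the labels' protocols, total RNA was size-selected to 15 to 50 nt, ligated to adapters, reverse transcribed, amplified over 20 PCR cycles and sequenced on an Illumina GAIIx, and reads were called with Illumina Pipeline 1.5. No molecular identifiers are described, so PCR copies count as separate reads, and all intervals and floors given cover counting error only. Ligation and amplification favour some sequences over others, so levels of different miRNAs within a library are less comparable than levels of the same miRNA between libraries prepared alike.

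Per the file headers, the authors mapped reads to miRNAs and precursors of selected species in miRBase and then mapped precursors and reads to genome and transcript sequences. Each entry has a group that says which of these placements it had, and hairpins predicted from the genome form a group of their own. The aligner, the miRBase release and the genome build are not given in the sources used here, and no coordinates are given for that reason. The gene table supplied for the species was not used.

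The deposited values are expected counts: reads per mature sequence and precursor, not normalised, with reads that match several precursors divided among them. Between 74.9% and 81.6% of the values in a library were whole to within 1e-09. In each file 6 to 8 lines are not analysed here (8, 8, 7, 7 and 6 in time order), so totals are over the other lines. No sample's columns carry values of another series.

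Entries were summed into 335 known mature miRNAs by name and arm, without the species prefix and the variant note, and names without a letter were joined with letter a within an arm. Sequences listed under more than 1 mature miRNA numbered 6 and held 0.231% of reads; the miRNAs concerned include miR-30d and miR-30e, miR-29a and miR-29c, and miR-1a and miR-1b, whose split is uncertain. Predicted hairpins stayed out of totals and ratios. Levels are RPM, reads-per-million reads on known miRNAs. This scale is relative: a miRNA that takes most of a library lowers all others.

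Each time was compared with normal liver for miRNAs with at least 100 reads in at least 1 of the 2 libraries. Counts were rounded to whole reads, and the ratio of levels was given an exact conditional binomial (Clopper-Pearson) 95% interval. A miRNA was called higher or lower when the ratio was at least 2-fold and the interval excluded 1. With 1 library per group no test across animals exists and no p-value is given. Where a library had 0 reads, the ratio was set against 3 reads and is given as a bound. Log2 ratios used a pseudocount of 0.5 reads.

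The tests, the miRNA lists, the naming rule and most alternatives were fixed before the data were examined. The lists were liver, rodent-higher and rodent-lower (described as rising or falling after hepatectomy in rodents), let-7, miR-17-92, blood cell, immune cell, endothelial, stromal, epithelial, muscle, neural, pancreas and gut, miR-29, miR-30, miR-125/99, miR-23/27/24 and stress. They rest on general knowledge of other vertebrates, and several hold miRNAs that liver also expresses. A list used members with at least 100 reads in at least 1 of the 5 libraries, and its median was ranked among 10000 random lists matched on mean expression, as a description of these libraries. Named miRNAs were drawn, per comparison, from the 8 largest and 8 smallest ratios whose interval excludes 1, the 10 most abundant miRNAs of normal liver, the 2 most-read members of each list, and miR-122, miR-21, let-7a and miR-451. Other named miRNAs were chosen after their values were seen.

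Alternatives were other totals, median-of-ratios factors (DESeq2 1.42.0) and TMM factors (edgeR 4.0.16) in R 4.3.3, other read minimums, fold thresholds and pseudocounts, the main sequence of each miRNA alone, miRNA families, and thinning of all libraries to the smallest. The 24 h library as the reference, totals without miR-122-5p and miR-99a-5p, and calls within lists and in opposite directions under the other scalings were added after seeing the data. The remaining work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

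The ratio step was tested on simulated data drawn from the normal library with 200 miRNAs changed by known folds. At the 3 h depth, the intervals held the true ratio for 92.7% of 110 tested miRNAs, and 6 of 6 miRNAs truly at least 3-fold higher and 13 of 15 at least 3-fold lower were called. At the 6, 12 and 24 h depths, the intervals held it for 99.1% of 117, 95.5% of 112 and 94.4% of 108, and all such changes were called. At the 12 h depth no tested miRNA was truly at least 3-fold higher, so calls of that direction were not tested there. No simulated library was filled by miR-122-5p as the 6 h and 12 h libraries were. The list step placed 5.5% of 200 unchanged random lists, and 96% of 200 lists raised 2-fold, at or above percentile 95. The log2 ratios simulated for it were much less spread than those observed at 3, 6 and 12 h. The quartiles of the tested miRNAs were 0.27 and 2.34 at 3 h, −7.11 and −1.82 at 6 h, and −6.31 and −1.23 at 12 h. The 96% therefore does not apply to these times.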

Results

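Small RNA was sequenced from the liver of the whitespotted bamboo shark, Chiloscyllium plagiosum, a small cartilaginous fish. The series holds 1 library of normal liver and 1 library each of liver taken 3, 6, 12 and 24 h after a partial hepatectomy, the surgical removal of part of the liver, after which the remaining tissue regrows in vertebrates. The 5 libraries address which microRNAs (miRNAs), short RNAs that restrain the translation and stability of messenger RNAs, differ between resting and regrowing liver. With 1 library per group there is no replicate check: intervals cover counting error only, and every difference is one between these libraries, not between conditions. The labels do not say whether the libraries came from different animals.

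Reads assigned to known miRNAs numbered 3864298 in the library labelled normal liver, 563316 at 3 h, 6173537 at 6 h, 4780855 at 12 h and 2120525 at 24 h. In this order, 240, 288, 228, 237 and 241 mature miRNAs had reads, and 109, 98, 63, 67 and 100 of them had at least 100 reads. A count of 0 allows up to 0.776, 5.33, 0.486, 0.628 and 1.41 RPM (reads-per-million known miRNA reads), in the same order.

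The most abundant miRNA was not the same in all libraries. miR-99a-5p (AACCCGTAGATCCGATCTTGT) took 45.6% of known miRNA reads in normal liver and 40.7% at 24 h, and miR-26a-5p (TTCAAGTAATCCAGGATAGGCT) led at 3 h with 13.1%. miR-122-5p (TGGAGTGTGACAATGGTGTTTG), the most abundant miRNA of hepatocytes in the vertebrates studied, took 81.5% at 6 h and 78.7% at 12 h. It had 10 reads in the library labelled normal liver, 48 at 3 h and 5 at 24 h, which are 2.59, 85.2 and 2.36 RPM. These 3 libraries therefore hold almost none of a miRNA that liver RNA is known for, so groups are named below by their labels only, and each direction given against normal is one against the library labelled normal liver. The 10 most abundant miRNAs made up 83.1% of reads in normal liver, 63.7% at 3 h, 98.6% at 6 h, 98.1% at 12 h and 81.7% at 24 h.

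**Figure D1:**
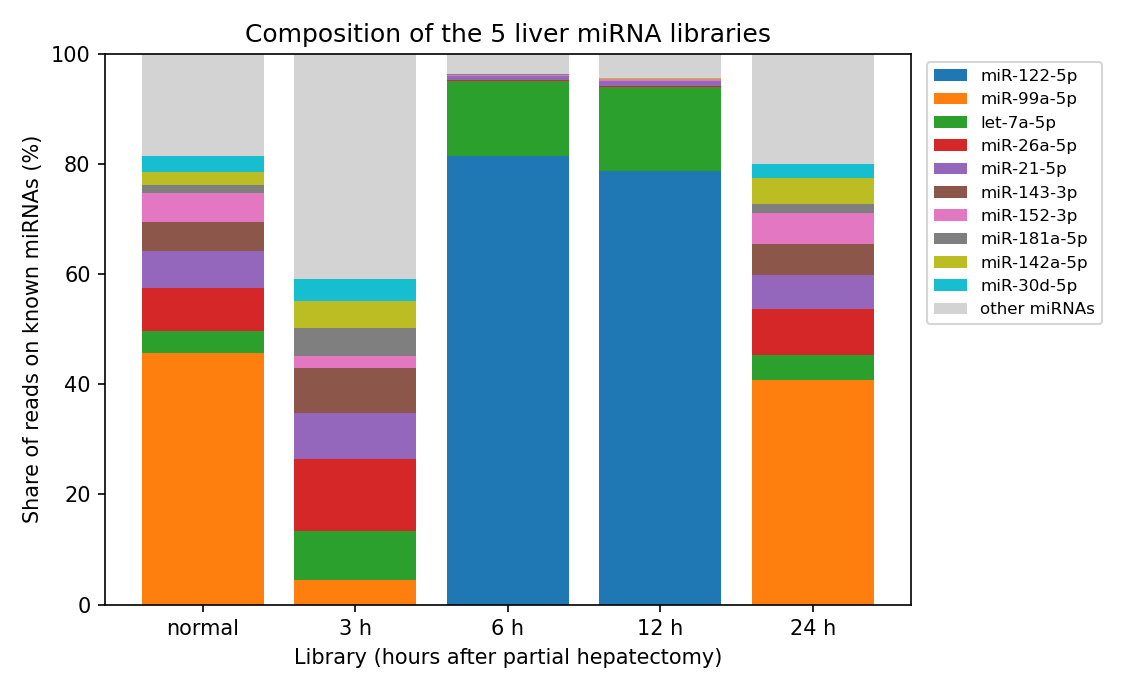
Share of known miRNA reads (%, vertical axis) taken by 10 named miRNAs and by all others in each of the 5 libraries (horizontal axis). miR-122-5p fills 81.5% and 78.7% of the 6 h and 12 h bars, and miR-99a-5p fills 45.6% and 40.7% of the normal and 24 h bars.

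At 3 h, miRNAs near or below detection in normal liver showed the largest ratios. miR-450a-5p, miR-130a-3p and miR-351-5p had no read in normal liver and were at least 636-fold, 514-fold and 254-fold higher at 3 h, from 278, 225 and 111 reads. miR-99b-5p was 1002-fold higher (95% interval 275 to 8309), miR-191-5p 317-fold (122 to 1177), miR-301a-3p 183-fold (127 to 273), miR-33a-5p 129-fold (87.2 to 199.9) and let-7f-5p 80.4-fold (51.4 to 132). miR-33 lies within genes of sterol regulation in vertebrates. The deposited annotation placed none of the reads of miR-450a-5p, miR-351-5p, miR-99b-5p and miR-191-5p at 3 h on the genome or transcript sequences it used. It left 1.78% of the reads of miR-130a-3p unplaced, 0.499% of those of miR-301a-3p, and 0% of those of miR-33a-5p and let-7f-5p. miR-99a-5p was 10.4-fold lower than in normal liver, miR-221-5p 8.13-fold, miR-10b-5p 3.65-fold, miR-145a-3p 3.46-fold and miR-204-5p 3.37-fold. miR-200b-3p, miR-3964-3p and miR-148b-3p were 3.35-fold, 3.18-fold and 2.73-fold lower.

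All 5 measured members of the blood cell list were at least 2-fold higher at 3 h than in normal liver. Among them were miR-144-3p at 10.3-fold and miR-451-5p at 8.98-fold, both abundant in red blood cells, with intervals of 9.81 to 10.8 and 6.99 to 11.6. Of the 6 immune cell miRNAs 5 were higher and none lower, with miR-181a-5p at 3.28-fold and miR-142a-5p at 2.08-fold. In the miR-17-92 list, linked to cell proliferation, 7 of 10 were higher and none lower, and its member miR-363-3p was 4.17-fold higher while miR-92a-3p differed by a ratio of 0.967. Of the 8 let-7 miRNAs 5 were higher, with let-7a-5p at 2.20-fold and let-7i-5p at 4.10-fold. In the list of miRNAs described as rising after hepatectomy in rodents, 3 of 6 were higher, miR-221-3p at 3.16-fold and miR-34a-5p at 5.14-fold among them, 1 was lower, and miR-21-5p stood at a ratio of 1.26. miR-210-3p, induced by low oxygen in many cells, was 13.7-fold higher (11.2 to 16.8), and 2 of the 3 stress miRNAs were higher. The epithelial list had 2 of 6 lower and none higher.

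In total 65 of 120 tested miRNAs were at least 2-fold higher at 3 h and 12 were lower, with intervals that exclude equality. The median log2 ratio of all tested miRNAs was 1.08, so that 35 lay at least 2-fold above and 26 at least 2-fold below this median. Scaling by the median of ratios gave 25 higher and 42 lower. Under that scaling and under TMM, 21 of the 65 miRNAs called higher changed to below normal, and of the named miRNAs among them these were let-7a-5p, miR-125b-5p, miR-126-3p, miR-142a-5p, miR-221-3p, miR-29b-3p and miR-30c-5p. So did miR-21-5p, miR-26a-5p, miR-143-3p, miR-30d-5p and others with a ratio between 1 and 2, for 16 named miRNAs in all, and the medians of 13 lists. With miR-122-5p and miR-99a-5p out of the totals 8 of these 16 changed to below normal, none of them called, so their direction at 3 h depends on the scaling. The lists concerned are liver, rodent-higher, rodent-lower, let-7, miR-17-92, immune cell, stromal, neural, pancreas and gut, miR-29, miR-30, miR-125/99 and miR-23/27/24. With median of ratios the blood cell list had 2 of 5 higher at 3 h, the immune cell list 1 higher and 1 lower, the miR-17-92 list 2 and 2, the let-7 list 2 and 1, the stress list 1 and 1, the rodent-higher list none and 3, and the epithelial list 6 of 6 lower.

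At 6 h, miR-122-5p stood at 814643 RPM against 2.59 in normal liver, a ratio of 314802 (171178 to 656469). Its opposite arm, miR-122-3p, had 521 reads against none, at least 109-fold higher. The striated muscle miRNAs miR-1a-3p and miR-1b-3p, which share a sequence so that their split is uncertain, were 199-fold (85.1 to 614) and 165-fold (45.4 to 1365) higher, from 5 and 2 reads in normal liver. let-7f-5p was 20.2-fold higher, miR-193b-5p 14.0-fold, miR-192-5p 7.65-fold and miR-456-3p 6.54-fold. The abundant let-7a-5p was 3.36-fold higher, the cartilage-enriched miR-140-3p 3.05-fold and miR-375-3p, known from pancreatic islets, 3.08-fold.

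The lower miRNAs at 6 h included most of the vascular, blood and connective tissue lists. miR-10b-5p had 2 reads against 40889 and was 32662-fold lower, miR-99a-5p was 5397-fold lower, miR-145a-3p 3707-fold and miR-126-3p, the endothelial miRNA, 2414-fold. miR-155-5p, induced in activated leukocytes, was 1275-fold lower, miR-205-5p 504-fold, miR-20a-5p 446-fold and miR-7b-5p 430-fold. All 5 blood cell, all 4 endothelial and all 6 epithelial miRNAs were lower, as were 5 of 6 immune cell and 9 of 10 stromal miRNAs, the exception in the last list being miR-140-3p. The miR-30, miR-23/27/24 and miR-29 lists were lower in 6 of 6, 6 of 6 and 3 of 3 members, and the miR-17-92 list in 8 of 9 tested. Of the miRNAs described as rising after hepatectomy in rodents 5 of 6 were lower, with miR-21-5p 9.44-fold and miR-34a-5p 3.71-fold, and all 3 tested of those described as falling were lower, with miR-26a-5p at 76.8-fold. The liver list had 3 higher and 6 lower: beside both arms of miR-122 and miR-192-5p, miR-101a-3p was 14.8-fold lower.

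Counted over 117 tested miRNAs, 15 were at least 2-fold higher and 91 lower at 6 h, and the median log2 ratio was −4.83, or 28.4-fold lower. Relative to this median, 44 lay at least 2-fold above and 48 at least 2-fold below. The median of ratios scaling gave 35 higher and 63 lower, and with it 16 of the miRNAs called lower stood above normal. Of the named miRNAs, miR-21-5p, miR-29a-3p, miR-34a-5p and miR-128-3p were among these. miR-210-3p and miR-221-3p, which had not been called lower, also moved above normal, as did the medians of the liver, rodent-higher and stress lists. The endothelial, miR-30 and immune cell lists then had as many lower as in RPM, with 1 immune cell miRNA higher. Of the blood cell list 4 of 5 were lower, of the epithelial list 5 of 6, of the miR-23/27/24 list 3 of 6 and of the miR-29 list 2 of 3. The stromal list had 3 higher and 6 lower of 10, and the miR-17-92 list 1 higher and 5 lower of 9. The rodent-higher list had 3 higher and 2 lower, the rodent-lower list 2 lower, and the liver list 5 higher and 3 lower.

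At 12 h the miRNAs at both extremes were largely those named at 6 h. miR-122-5p had 787445 RPM, a ratio of 304292 (165463 to 634552), and miR-122-3p was at least 259-fold higher from 963 reads. miR-1a-3p was 474-fold higher (203 to 1462), miR-1b-3p 431-fold (119 to 3562), let-7f-5p 34.6-fold, miR-193b-5p 16.4-fold, miR-192-5p 11.1-fold and miR-456-3p 7.47-fold. let-7a-5p was 3.76-fold, miR-140-3p 3.12-fold and miR-375-3p 5.38-fold higher. miR-10b-5p was 10117-fold lower, miR-99a-5p 2882-fold, miR-145a-3p 2488-fold, miR-140-5p 1301-fold and miR-126-3p 1169-fold. miR-20a-5p, miR-155-5p and miR-7b-5p were 425-fold, 411-fold and 399-fold lower. All measured blood cell, endothelial, epithelial, miR-30, miR-23/27/24 and miR-29 miRNAs were again lower, with 5 of 6 immune cell and 8 of 10 stromal miRNAs. The miR-17-92 list had 8 of 9 tested lower and 1 higher, the liver list 3 higher and 6 lower, the rodent-higher list 5 of 6 lower and the rodent-lower list 3 of 3 tested lower. The let-7 list had 3 higher and 2 lower of 7 tested at 6 h and at 12 h, and the stress list 2 of 3 lower at both, but with median of ratios the let-7 list had 5 higher and 2 lower and the stress list 3 of 3 higher at both times. miR-451-5p was 8.74-fold lower at 12 h and 90.3-fold lower at 6 h, from 16 and 2 reads.

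Of 117 miRNAs tested at 12 h, 17 were at least 2-fold higher and 88 lower, with a median log2 ratio of −4.51, and 50 and 39 lay at least 2-fold above and below that median. The median of ratios scaling gave 36 higher and 63 lower, and 13 of the miRNAs called lower then stood above normal. Of the named miRNAs, miR-29a-3p and miR-34a-5p were among these. miR-128-3p, miR-210-3p and miR-221-3p, which had not been called lower, also moved above normal, as did the medians of the liver, rodent-higher and stress lists. All endothelial, epithelial and miR-30 miRNAs were still lower, but the blood cell list had 1 higher and 3 lower, the stromal list 3 and 6, the rodent-higher list 3 and 2, the liver list 5 and 3, the immune cell list 1 and 5, the miR-17-92 list 1 and 6, the miR-23/27/24 list 3 of 6 lower, the miR-29 list 2 of 3 and the rodent-lower list 2 of 3 tested. The 6 h and 12 h comparisons shared 15 higher and 88 lower miRNAs among 117 tested in both. In 100 simulations of unchanged libraries against the same normal library none were shared, a value that leaves out the effects and holds counting error only. Independent lists of these sizes would share 2.18 and 68.4, values that leave out the shared normal library. Part of the overlap may come from the shared normal library, and that part was not separated here. Compared with each other directly, without the normal library, the 6 h and 12 h libraries had a Spearman's rho of 0.987.

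At 24 h the library was close to that of normal liver: of 111 tested miRNAs 8 were at least 2-fold higher and none at least 2-fold lower, and the median log2 ratio was 0.05. The higher miRNAs were miR-6087-3p at 33.8-fold (30.4 to 37.6), miR-3963-5p at 5.02-fold (3.42 to 7.53), miR-144-3p at 3.08-fold (2.95 to 3.23), miR-6087-5p at 2.66-fold (2.24 to 3.17), miR-451-5p at 2.52-fold (1.96 to 3.23), miR-192-5p at 2.09-fold (1.57 to 2.77), miR-193b-5p at 2.05-fold (1.77 to 2.38) and miR-194-5p at 2.00-fold (1.83 to 2.20). Of the blood cell list 2 of 5 were higher, and of the liver list 2 of 8 tested, of which none remained with median of ratios or TMM, while the blood cell list had 2 higher with both. The smallest ratios belonged to miR-200a-3p at 0.601 (0.502 to 0.718), miR-204-5p at 0.655, miR-455-3p at 0.687, miR-222-3p at 0.693, miR-200b-3p at 0.698, miR-205-5p at 0.710, miR-139-5p at 0.712 and miR-199-5p at 0.734. miR-99a-5p stood at a ratio of 0.892, miR-21-5p at 0.917 and let-7a-5p at 1.12. The median of ratios scaling left 5 higher and none lower, and placed 8 named miRNAs with ratios just over 1, let-7a-5p and miR-26a-5p among them, below normal.

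**Figure D2:**
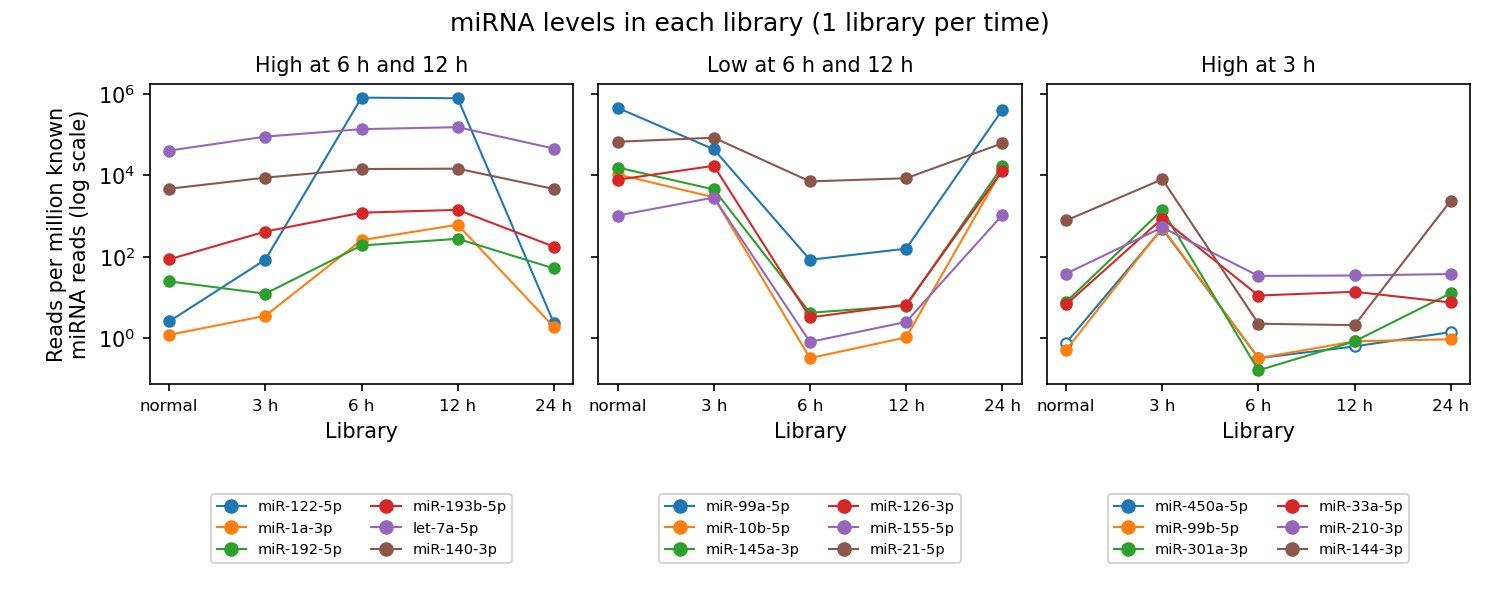
RPM (log scale, vertical axis) of 18 named miRNAs in the 5 libraries (horizontal axis); each point is 1 library, and an open circle marks 0 reads, drawn at the level 3 reads would give. miR-122-5p goes from 2.59 in normal liver to 814643 at 6 h and back to 2.36 at 24 h.

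Over all 5 libraries, 128 miRNAs had at least 100 reads in at least 1. The 3 h library held the highest level for 87 of them (68.0%) and the 6 h library the lowest for 87. Normal liver was highest for 13 (10.2%) and lowest for 16 (12.5%), where exchangeable libraries would give 20% each. Across these miRNAs, which are not independent replicates, Spearman's rho was 0.982 between normal liver and 24 h and 0.987 between 6 h and 12 h. It was 0.832 between normal liver and 3 h, 0.842 between 3 h and 24 h, and between 0.457 and 0.481 for the 6 pairs that set 6 h or 12 h against another library. Both close pairs still differed by more than counting error, with chi-square per degree of freedom of 489 for normal liver and 24 h and 150.3 for 6 h and 12 h, so neither pair is 1 library deposited in duplicate. The time of sampling cannot be told apart from the animal or the library.

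The medians of the fixed lists were set against the median of all 128 miRNAs, which stood at log2 ratios of 1.10, −4.61, −3.92 and 0.08 at 3, 6, 12 and 24 h, and against 10000 random lists matched on expression. The let-7 list lay 5.49 and 5.06 above that median at 6 h and 12 h, at percentile 99.9 in both, and at percentiles 60.5 and 93.95 at 3 h and 24 h, with a median of 0.89 at 6 h where its mean was −0.23. The endothelial list lay furthest below, by −3.96 and −3.88 at percentiles 0.10 and 0.79, and at 24 h it was at percentile 96.1. At 3 h its median of −0.05 and mean of 0.39 differed in sign at percentile 4.74. Its members were split there: miR-126a-5p and miR-126-3p were 11.7-fold and 2.21-fold higher, and miR-10a-5p and miR-10b-5p 2.37-fold and 3.65-fold lower. The epithelial list was at percentiles 0.16, 12.8, 0.08 and 0.63 at 3, 6, 12 and 24 h. The blood cell list was at percentiles 83.1, 12.9, 11.2 and 99.1, the immune cell list at 80.8, 9.18, 11.5 and 54.1, and the stromal list at 16.7, 12.1, 14.8 and 20.6. The muscle list, of 2 miRNAs with a shared sequence, was at percentile 100 at 6 h and 12 h and at 52.7 and 92.7 at 3 h and 24 h, where neither miRNA had 100 reads. Both passed the read minimum only through the 6 h and 12 h libraries, so a high rank there follows in part from that filter. The other families of this list had no member with 100 reads in any library. The liver list was at percentiles 1.94, 90.2, 89.9 and 92.2, with medians of −2.71 and −2.22 and means of 0.09 and 0.61 at 6 h and 12 h. The rodent-higher list was at percentiles 52.9, 82.5, 78.6 and 0.53, and the rodent-lower list at 27.1, 26.2, 26.6 and 73.6.

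Among the remaining lists, the miR-17-92 list was at percentiles 68.4, 6.16, 21.7 and 2.65 at 3, 6, 12 and 24 h. At 6 h its median was −6.43, or −5.44 with a miRNA at 0 reads set to its bound. The miR-29 list was at percentiles 38.4, 25.6, 27.6 and 39.6, with a 6 h median of −7.34, or −5.79 with the bound. The miR-30 list was at 39.99, 22.4, 19.3 and 13.8, the miR-125/99 list at 72.95, 44.5, 47.5 and 46.95, the miR-23/27/24 list at 19.8, 32.1, 26.3 and 26.8, and the stress list at 88.4, 84.6, 84.7 and 31.4. The neural list of 2 miRNAs was at 51.1, 31.85, 37.6 and 28.5, with a 6 h median of −4.93, or −3.63 with the bound, and the pancreas and gut list, of miR-375-3p alone, at 24.99, 94.9, 90.1 and 35.5. miR-375-3p passed the read minimum only through the 6 h and 12 h libraries, so its rank there follows in part from that filter. The epithelial 12 h median was −7.26, or −6.80 with the bound.

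**Figure D3:**
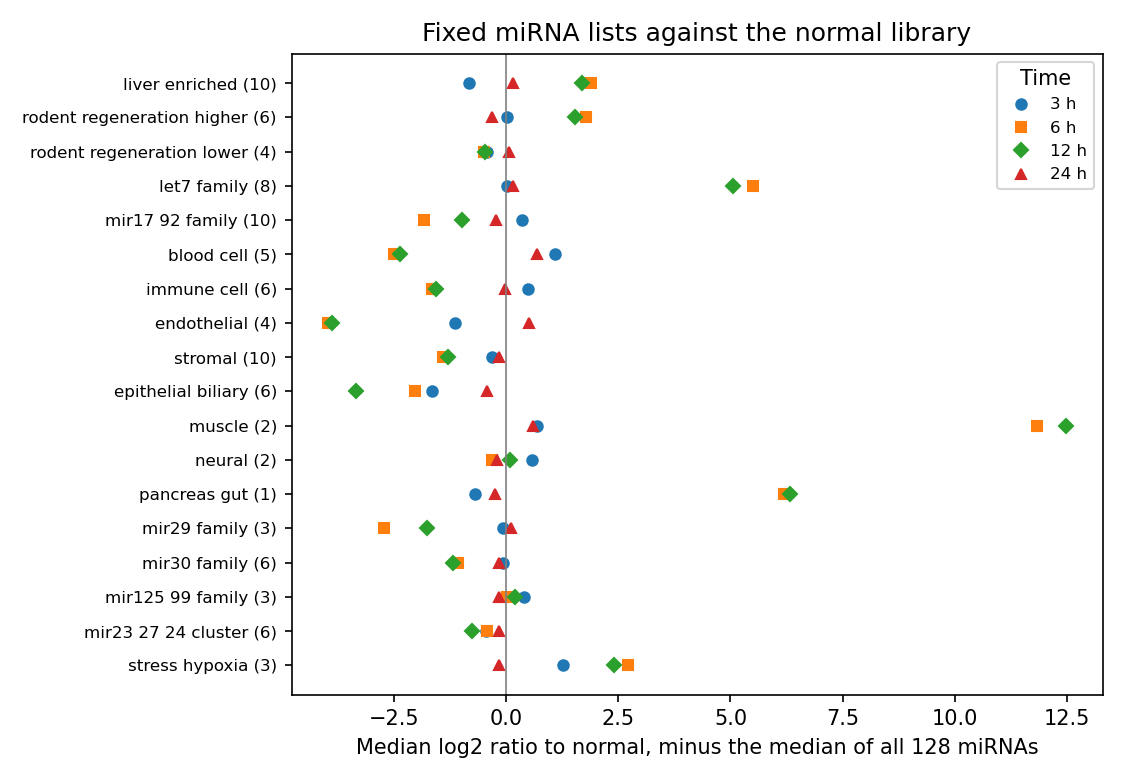
Median log2 ratio of each fixed miRNA list to normal liver after subtraction of the median of all 128 miRNAs (horizontal axis, log2), with the number of measured members in brackets, for the 3, 6, 12 and 24 h libraries. The let-7 list lies 5.49 and 5.06 above the median at 6 h and 12 h, and the endothelial list at −3.96 and −3.88.

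Sequence length and arm use also differed between libraries. By the representative sequence of each entry, 21 nt sequences took 61.2% of known miRNA reads in normal liver, 26.4% at 3 h, 0.751% at 6 h, 1.05% at 12 h and 60.1% at 24 h, while 22 nt sequences took 20.0%, 39.8%, 96.3%, 95.6% and 21.6%. miR-99a-5p has 21 nt and miR-122-5p 22 nt. Among 44 miRNAs with both arms of the hairpin listed and at least 20 reads on the arms together in each library, the share of the 5p arm differed by over 25 percentage points between normal liver and 6 h, with separate exact binomial intervals, for 10. At 3 h 3 miRNAs differed by over 25 points from normal liver, namely miR-142a, miR-221 and miR-30a, and at 24 h 1, miR-6087.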

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

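The tests in this part were chosen after the results were seen, except that the prediction for the share of miRNAs highest at 3 h was written before that share was computed, though after the shift of the median under the same setting was known.

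Reads on predicted hairpins, which no comparison above uses, made up 5.10% of all listed reads at 3 h and 2.36% at 24 h, against 1.67% (1.66 to 1.69) in normal liver, 0.117% at 6 h and 0.146% at 12 h. A single predicted hairpin supplied 17920 of 30248 such reads at 3 h, 28928 of 51253 at 24 h and 32496 of 65776 in normal liver. The number of miRNAs at least 2-fold higher at 3 h and at least 2-fold lower at 6 h, both against normal liver, was 41, and it was 40 for 3 h and 12 h. Of 110 miRNAs tested at both 3 h and 6 h, 55 were higher at 3 h and 91 lower at 6 h. For 3 h and 12 h these were 55 and 88 of 110. Independent calls would therefore also place most of the 55 in opposite directions. With median of ratios or TMM scaling the 41 and 40 became 8 and 7. These opposite directions rest on 1 library each, and the difference was not tested.

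miR-122-5p filled most of the 6 h and 12 h libraries and almost none of the other 3. A gap in the mapping or filtering of this sequence alone was set against the opposite arm. At the 6 h share 326 reads of miR-122-3p would be found in the normal library, and none were. This goes against such a gap only if miR-122 used its arms alike in both libraries, which cannot be checked. Arm use differed between them by over 25 points for 10 of 44 miRNAs, with the 5p share of miR-363 at 0.425% in normal liver and 49.8% at 6 h. A gap over both arms would also leave none, as would a miR-122-3p line among those not analysed, so neither is excluded. An exchange of labels among the libraries stays open: 3 libraries had under 100 RPM, a number that is the same under any exchange and does not say which times they belong to. RNA of other cell types or of another tissue in those 3 libraries cannot be told apart from a change with time. With miR-122-5p and miR-99a-5p out of the totals, all 5 of the blood, immune, endothelial, stromal and epithelial lists were over 2-fold higher there than at 6 h and 12 h. So was the median miRNA. The neural list was at least 4.73-fold higher there, and the liver list 1.83-fold to 2.74-fold higher. The muscle, let-7, and pancreas and gut lists were lower there. Of the first 5 lists 1, the endothelial one, stood at or under percentile 5 at both 6 h and 12 h, a rule that replaced the first once its outcome was seen. The hours after hepatectomy remain an untested biological explanation, as does a difference between animals.

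The 3 h library held the highest level of most miRNAs. A mixture of RNA like that of the normal library with RNA like that of the 6 h library is argued against, since 47.7% of 128 miRNAs were over 2-fold higher at 3 h than in both. A smaller share of the most abundant miRNAs was not decided. With miR-122-5p and miR-99a-5p out of the totals, 45.2% of miRNAs were still highest at 3 h, against 68.0% before. By the rule set in advance, a share over 40% goes against this explanation, though the fall from 68.0% goes with it in part. An interval of 36.4 to 54.3, added after the first value was seen, includes 40%. It treats miRNAs of the same libraries as independent, which they are not, so it cannot decide. Reads from a mammal stay open as a source of some miRNAs nearly absent from the other 4 libraries. Families described in mammals were listed from general knowledge after miR-351-5p and miR-450a-5p were seen at 3 h. They summed to at least 61.6 times the level of any other library, and to at least 30.7 times without these 2 families. These ratios depend on the list, which held 39 reads in normal liver. It left out miR-3968-3p, with 7659 reads there, miR-6087 and miR-7641, and whether these belong on it was not tested. The listed families hold 0.139% of reads at 3 h and 2 of the 87 miRNAs highest at 3 h. They therefore leave the rest of the pattern open, with the time after hepatectomy untested.

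The arm taken differed between normal liver and the 6 h and 12 h libraries, while at 3 h miR-221 went with 6 h and 12 h, and at 24 h miR-6087 differed from normal liver too. Counting error is argued against by 10 of 44 miRNAs whose 5p shares lay over 25 points apart between normal liver and 6 h with separate intervals. A different ligation or sequencing batch cannot be told apart from the groups, since the labels give no batch and all 10 shifted in the same direction by over 25 points at 12 h. The time after hepatectomy is untested here too.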

How the results depend on the processing

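The 24 h reference, the totals without miR-122-5p and miR-99a-5p, and the calls within lists and in opposite directions under other scalings were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. Of the alternative counts of higher and lower miRNAs, 77 stayed within 1.5 times the value reported and 33 did not; using the 24 h library as the reference, all listed reads as the total, the main sequence of each miRNA, or leaving out sequences under 2 families moved no count by more. Log2 ratios of named miRNAs changed sign in 95 cases, 28 of them from a called difference, and list medians in 59, 31 of them from a median at least 2-fold from normal; these 28 and 31 are given below. Of the 5p shares 198 stayed and 22, all of let-7a, miR-199, miR-26a, miR-30a, miR-30c and miR-7641, moved with the main sequence of each arm. Under that setting the same 10 miRNAs lay over 25 points apart between normal liver and 6 h. For 10 shares of reads by length the alternative was the share of distinct sequences. That is a different quantity, so it does not check the shares of reads. Thinning lowered the number of miRNAs that reach 100 reads, which is its construction, as are the changes with the read minimum, the fold threshold and the family unit; the cause of the other changes was not tested. The 3 h library has the highest floor, 5.33 RPM.

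At 3 h, the 65 higher miRNAs became 25 with median of ratios, 25 with TMM, 103 with a minimum of 20 reads, 172 with none, 42 by family, 39 at 4-fold and 41 without miR-122-5p and miR-99a-5p in the total. The 12 lower became 42, 41, 2 at 4-fold and 19 without these miRNAs, the first 2 with median of ratios and TMM. At 6 h, the 15 higher became 35 with median of ratios, 31 with TMM, 27 with the most abundant miRNA out of the total, 25 with no minimum, 8 after thinning and 9 at 4-fold, and the 91 lower became 146 with no minimum and 58 by family. At 12 h, the 17 higher became 36, 34, 30 and 32 in that order, and 11 by family and 11 at 4-fold, and the 88 lower became 57 by family. At 24 h, the 8 higher became 5 with median of ratios, 5 with TMM, 3 with a higher read minimum, 14 with none, 5 after thinning, 2 at 4-fold and 5 without miR-122-5p and miR-99a-5p.

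At 3 h, the log2 ratios under median of ratios and TMM were −0.57 and −0.55 for let-7a-5p, −0.21 and −0.18 for miR-125b-5p, −0.57 and −0.55 for miR-126-3p, −0.66 and −0.63 for miR-142a-5p, −0.0520 and −0.0273 for miR-221-3p, −0.69 and −0.67 for miR-29b-3p, and −0.44 and −0.41 for miR-30c-5p. The list medians were −0.60 and −0.57 for rodent-higher, −0.60 and −0.58 for let-7, −0.26 and −0.23 for miR-17-92, −0.12 and −0.10 for immune cell, −0.0304 and −0.00566 for neural, −0.69 and −0.67 for miR-29, −0.69 and −0.66 for miR-30, and −0.21 and −0.18 for miR-125/99.

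At 6 h, miR-128-3p went to 2.40 and 1.77 under these scalings, to 1.24 with the most abundant miRNA left out and to 0.36 with miR-122-5p and miR-99a-5p left out. miR-34a-5p went to 1.70, 1.07 and 0.54 under the first 3, and miR-21-5p and miR-29a-3p went to 0.35 and 0.30 under median of ratios. The liver list went to 0.88 and 0.25, rodent-higher to 0.76 and 0.14, and stress to 1.70, 1.07 and 0.54. At 12 h, miR-29a-3p went to 0.27 and 0.0400, and miR-34a-5p to 1.13, 0.89 and 0.41. The liver list went to 0.72, 0.49 and 0.00978, rodent-higher to 0.55 and 0.31, and stress to 1.42, 1.18 and 0.70.

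The median log2 ratio over all tested miRNAs moved from 1.08 to −0.63 at 3 h, from −4.83 to −1.24 at 6 h, from −4.51 to −1.56 at 12 h and from 0.05 to −0.13 at 24 h under median of ratios.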

Other observations

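Arm use, given here for miRNAs chosen after their values were seen, differed between libraries, with the precursors under a name pooled. The 5p arm held 41.8% of miR-199 reads in normal liver, 65.1% at 3 h, 0.747% at 6 h, 0.968% at 12 h and 37.4% at 24 h. For miR-214, a stromal miRNA that is transcribed with miR-199 in vertebrates, it held 27.2%, 34.1%, 0.286%, 1.26% and 27.01%. miR-145a went the other way, with 21.7% and 18.7% in normal liver and at 24 h and 93.4% and 95.7% at 6 h and 12 h. For miR-363 the 5p share was 0.425% in normal liver and 49.8% at 6 h, and for miR-194 it was 74.7% and 21.6%. miR-221 had 48.6% in normal liver, 3.55% at 3 h, 3.05% at 6 h, 3.91% at 12 h and 48.3% at 24 h. For miR-6087, the miRNA with the largest ratio at 24 h, the 5p arm held 37.6% in normal liver, 33.7% at 3 h, 84.3% at 6 h, 80.9% at 12 h and 4.54% at 24 h. Both of its arms were also higher at 3 h than in normal liver, miR-6087-3p by 24.6-fold and miR-6087-5p by 20.7-fold.

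Within the let-7 family the members were not alike at 6 h: the 5p miRNAs let-7a-5p, let-7e-5p and let-7f-5p were 3.36-fold, 2.28-fold and 20.2-fold higher than in normal liver, and the opposite arms let-7a-3p and let-7b-3p were 124-fold and 25.3-fold lower. let-7e-5p and both opposite arms were named after their values were seen.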
